A study of Homo sapiens with 15 samples.

How the data were processed

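Gene expression was measured by RNA sequencing in 15 samples of human fetal liver haematopoietic stem and progenitor cells (HSPC). Per the labels, cells were sorted as CD34-positive, CD38-negative or low and CD90-positive, and were profiled either uncultured or after infection with a lentivirus and 4 weeks on OP9M2 stroma, when GFP-positive cells of the same surface phenotype were sorted. The groups were taken from the sample titles: 3 uncultured samples, 6 infected with the control vector and 6 infected with the MLLT3 vector. Per the labels' protocols, total RNA was extracted with a column kit and made into libraries with a kit that removes ribosomal RNA. Nothing in the labels says that the samples of a group came from separate donors or cultures, so p-values measure the spread between these samples.

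Per the submitters' processing notes, reads were handled with TopHat2 version 2.0.14 and bedtools on genome build hg19. Per the file headers, HOMER's analyzeRepeats counted tags over RefSeq exons of hg19, taking only reads on the strand opposite to the gene, and 1 transcript was kept per gene. The authors deposited the values of all 15 samples as RPKM, tags per kilobase of exon and per M tags of the sample, with replicates not pooled. A second deposited table holds, for the 12 cultured samples, a signal of gene reads that the authors scaled so that every sample sums to 6.84 M over genes. The authors' log2 fold changes in that table came from edgeR run through HOMER's getDiffExpression with the pair as a batch, per the file headers; the edgeR version is not given in the sources used here. The p-values and adjusted p-values that the authors deposited beside them came from the same paired comparison, per the file headers. Coordinates are those of the deposited table, on hg19. Counting by strand separates a gene from an overlapping gene on the other strand, but near-identical copies (globin genes, HSPA1A and HSPA1B, tryptases and trypsinogen-family genes) share reads, and their values are uncertain.

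Of the 26457 genes of the RPKM table, 118 (Y-linked genes, XIST and TSIX) were left out and 26339 were used. Older symbols were matched by name where a list member had been renamed. Table columns were mapped to samples by the library names in the submitters' descriptions, and 0 columns of other samples were present. Library totals were 12.3 to 15.5 M tags; for the 12 cultured samples they are in the header, and for the 3 uncultured samples they were derived from the spacing of the low RPKM values. Values in both tables are whole multiples of what 1 read is worth: with a tolerance of 0.1 read, 100% of the values in the scaled table and at least 96.7% in the RPKM table (transcripts up to 5000 bases) were whole in every sample. The lowest chi-square per degree of freedom between 2 libraries of a group was 8.77, so no library was a copy of another within sampling noise.

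The design had provided for whole counts, and the deposited tables hold RPKM and scaled gene reads, so the test planned for RPKM was used. Tests were run with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with trend and robust settings, over genes with an RPKM of at least 1 in at least 3 samples of the fit. A fold change is therefore on the log2(RPKM + 1) scale, which understates the change of low genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and all adjusted p-values of single genes below are limma's. For MLLT3 against control the fit held the 12 cultured samples with the pair as a block, as in the authors' own paired test; the pairing comes from the submitters' descriptions and the header of their table, which name 6 pairs. Deviations from the group means correlated at 0.35 to 0.52 across genes between same-numbered control and MLLT3 samples and at most 0.18 between other numbers, and 6 of 6 control samples correlated best with their own number. Both comparisons with uncultured cells used 1 fit of all 15 samples with a term per group and no block, since no source pairs uncultured with cultured samples.

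Simulated data had 200 changed genes and, unlike real libraries, equal shares of exonic tags. The fit for MLLT3 against control (12618 genes) recovered 65.2%, 80.3% and 98.5% of genes changed 1.5-, 2- and 4-fold, and 3.03% of its calls were false. For control against uncultured (12874 genes) recovery was 43.3%, 71.2% and 95.4%, with 4.17% false, and for MLLT3 against uncultured (12852 genes) 44.6%, 77.3% and 90.6%, with 4.83% false. In simulated lists of uncorrelated genes, unlike real ones, camera called 20 of 20 shifted by log2 0.3 and 0 of 20 unshifted.

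Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over a comparison's lists, beside fry and camera with an estimated correlation. The 26 lists were HSC regulators and surface markers, HOXA and HOXB cluster genes, DOT1L and elongation complex partners, fetal program genes, erythroid genes, megakaryocyte genes, granulocyte and monocyte genes, mast cell, basophil and eosinophil genes, dendritic cell genes, MHC class II genes, B cell genes, T and NK cell genes, endothelial genes, hepatocyte genes, stromal genes, interferon-stimulated genes, inflammatory and NF-kB genes, immediate early genes, heat shock genes, S phase genes, G2 and M phase genes, cell cycle inhibitors and p53 targets, cholesterol synthesis genes, glycolysis and hypoxia genes, homing and niche receptor genes, and small noncoding and nuclear RNAs. The groups, comparisons, tests, lists, the rule for named genes and the other settings were fixed before the data were examined.

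Named genes are MLLT3 and, in each comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean RPKM of at least 1 in the higher group that moved the same way in all 6 pairs, or whose groups did not overlap. Per list, up to 4 called members with the largest change are named, or the 2 of highest level where none was called. For the overlap of culture and MLLT3, up to 8 genes per direction follow the size of the MLLT3 change. Y-linked genes, XIST and symbols of clones, antisense, small and unnamed noncoding RNAs were left out of the rule for the largest changes. The text names fewer genes than the rule allows, in order of rank.

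The overlap of culture and MLLT3 calls was set beside the overlap of independent lists and all 20 splits of the controls into 3 and 3, and the covariance of the log2 changes beside a simulation of unchanged groups with shared controls. Simulated unchanged groups shared 0 calls in every run, which says nothing on the counts, so the simulation was not used for them. The distance to the uncultured group was the median, over genes that fell in control culture, of the level in each MLLT3 sample minus its paired control, with the genes chosen without the tested pair and an exact two-sided sign-flip permutation test over the 6 pairs. Other settings tried were pseudocounts of 0.1 and 0.5, no filter and a filter of RPKM 5, median centring, quantile normalization, TMM factors, limma without trend and robust settings, a 2-fold minimum, fits with and without blocks, each library left out in turn, and the groups of library names taken apart. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and voom on the whole reads rebuilt from the tables, and fits without 1 uncultured sample that keep the genes tested in the full fit; edgeR called 876 genes up and 915 down for MLLT3 against control, 2945 and 2987 for control against uncultured, and 3056 and 3160 for MLLT3 against uncultured. The random-effect block used statmod 1.5.0, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.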

Results

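Haematopoietic stem and progenitor cells of human fetal liver (HSPC) were profiled by RNA sequencing in 3 groups: 3 uncultured samples, 6 samples infected with a control lentiviral vector and 6 infected with a vector for MLLT3, a chromatin reader of elongation and DOT1L complexes that is known as a regulator of human stem cell maintenance. Both infected groups had spent 4 weeks on OP9M2 stroma, a mouse bone marrow stromal line, before GFP-positive HSPC were sorted. Sorting on CD34, CD38 and CD90 in all 3 groups shapes those genes' levels, yet the HSC list includes CD34 and CD90. Depth was alike, with mean library totals of 14.01 M tags in the uncultured, 14.4 M in the control and 14.1 M in the MLLT3 group. The share of tags in gene exons was 51.3% ± 2.28 (SD, n = 3) in the uncultured samples, 46.6% ± 2.75 (SD, n = 6) in controls and 46.7% ± 1.60 (SD, n = 6) with MLLT3. The design sets MLLT3 against control cells after culture, and each cultured group against uncultured cells.

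MLLT3 itself was higher in every sample that received its vector than in every other sample. The control samples held 8.04, 8.67, 7.68, 8.60, 8.32 and 8.41 RPKM, and the paired MLLT3 samples 20.8, 18.2, 17.8, 20.6, 27.7 and 38.5 RPKM. The uncultured samples held 9.11, 13.4 and 16.0 RPKM. Means were 8.29 ± 0.372 (SD, n = 6) in controls, 23.9 ± 7.97 (SD, n = 6) with MLLT3 and 12.8 ± 3.49 (SD, n = 3) uncultured. The gene (NM_001286691, 6675 bases of exon) lies on the minus strand of chromosome 9, 20341663 to 20621986, and exonic reads from the transgene and from the endogenous gene were counted together. MLLT3 rose over control by 1.37 on the log2(RPKM + 1) scale (SE 0.13, n = 6 pairs, adjusted p = 0.0017), by 1.14 in pairs 1 to 4 and 1.85 in pairs 5 and 6, which carry another series of library names, the one of the uncultured samples (difference 0.711, limma's unadjusted p of 0.00101, adjusted over all genes 0.451). Against uncultured cells MLLT3 rose by 0.83 (SE 0.20, adjusted p = 0.00321) in the MLLT3 group. In control culture MLLT3 fell by 0.54 (SE 0.20, adjusted p = 0.0365), a call that did not pass with no filter (0.0539), median centring (0.0975), quantile normalization (0.0945), TMM factors (0.125), edgeR (0.0913), voom (0.1065), only the libraries named like the uncultured ones (0.1405), a block by library code number (0.0725) or the series of names as a term (0.268); with 1 library left out its adjusted p ran from 0.0138 to 0.185, above 0.05 without uncultured sample 2 or 3 or control 1, 3 or 6.

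**Figure D1:**
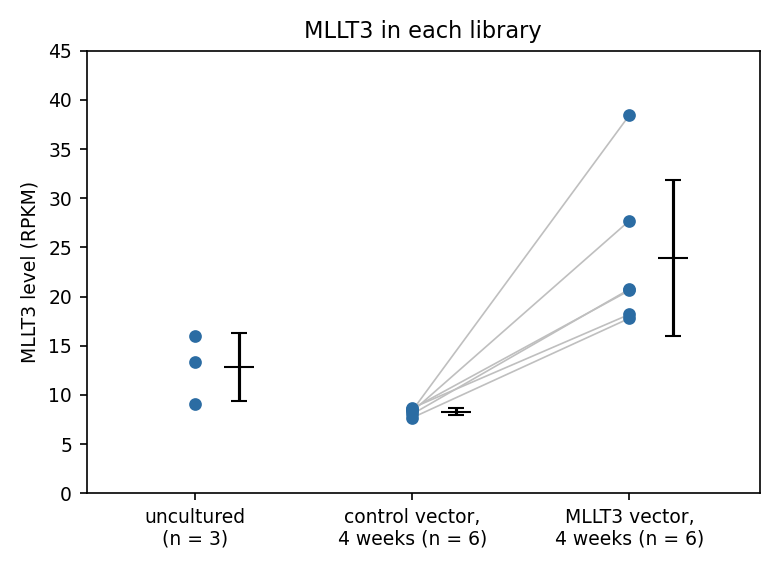
MLLT3 level (RPKM, vertical axis) in each of the 15 samples by group, with lines joining the 6 pairs of control and MLLT3 samples and bars giving the mean ± SD. The 6 MLLT3 samples lie between 17.8 and 38.5 RPKM and the 6 controls between 7.68 and 8.67 RPKM.

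With MLLT3, cultured HSPC held more RNA of AVP and PROM1 and less of CYBB and MKI67. AVP, a transcript marking the most primitive HSPC, rose by 1.11 on the log2 scale (SE 0.12, n = 6 pairs, adjusted p = 0.00139), from 0.607 ± 0.456 to 2.36 ± 0.339 RPKM (SD, n = 6). PROM1, which encodes the surface protein CD133 of stem and progenitor cells, rose by 0.86 (SE 0.07, adjusted p = 0.00102), from 22.98 to 42.7 RPKM. The largest fall among the named coding genes was in CYBB, the catalytic subunit of the phagocyte NADPH oxidase, which fell by 1.49 (SE 0.10, adjusted p = 1.94e-04), from 39.7 ± 7.04 to 13.9 ± 4.48 RPKM. MKI67, the Ki-67 proliferation gene, fell by 0.62 (SE 0.12, adjusted p = 0.0234), from 48.8 to 31.8 RPKM. Of 12558 genes tested, 303 rose and 302 fell, and 550 of these 605 moved the same way in all 6 pairs.

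Other genes with large rises were KIAA0087, a long noncoding RNA (log2 change 1.05, SE 0.10, adjusted p = 0.00102, 26.9 to 57.0 RPKM), IGFBP2, a binding protein of insulin-like growth factors (0.90, SE 0.10, adjusted p = 0.00137), and SDK2, a cell adhesion molecule (0.87, SE 0.10, adjusted p = 0.00321). SKAP1, an adaptor of T cell receptor signalling, rose by 0.86 (SE 0.11, adjusted p = 0.00338), and IL1B, the cytokine interleukin-1 beta, by 0.82 (SE 0.10, adjusted p = 0.00439). Among the falls, RPS6KA2, a ribosomal S6 kinase, decreased by 1.11 (SE 0.10, adjusted p = 0.00102). CSF1R, the macrophage colony-stimulating factor receptor, decreased by 0.98 (SE 0.20, adjusted p = 0.0371); this adjusted p reached 0.139 with 1 pair left out and was above 0.05 without pair 1, 2, 4, 5 or 6. PRSS3P2, a trypsinogen-family pseudogene whose reads are shared with its relatives, decreased by 0.86 (SE 0.09, adjusted p = 0.00102). CDKN2C, an inhibitor of CDK4 and CDK6, decreased by 0.83 (SE 0.09, adjusted p = 0.00137). RBMS3, an RNA-binding protein, decreased by 0.82 (SE 0.08, adjusted p = 0.00102), IL13RA1, an interleukin-13 receptor chain, by 0.82 (SE 0.12, adjusted p = 0.00679), and TRIB2, a pseudokinase, by 0.80 (SE 0.11, adjusted p = 0.00487). By the naming rule (same direction in all 6 pairs), these genes keep their sign in pairs 1 to 4 and in 5 and 6.

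HSC regulators and surface markers moved up as a list: 14 of 36 measured members rose, 0 fell and 22 did not pass, or 19 and 0 adjusted over the list alone, with a median log2 change of 0.22. Camera's adjusted p was 1.15e-11 (adjusted p = 0.295 with an estimated correlation). Besides AVP and PROM1, the list's largest rises were in HLF, a transcription factor of haematopoietic stem cells (0.74, SE 0.09, adjusted p = 0.00253, 17.3 to 29.7 RPKM), and KIT, the stem cell factor receptor (0.61, SE 0.10, adjusted p = 0.0146, but 0.0509 without pair 2). The list median was 0.189 over pairs 1 to 4 and 0.3502 over pairs 5 and 6. Of 12 measured HOXA and HOXB cluster genes, 5 rose, 0 fell and 7 did not pass, or 7 and 1 adjusted over the list alone (median 0.27). By camera the adjusted p was 6.72e-06 (adjusted p = 0.295 with an estimated correlation). HOXA6 rose by 0.51 (SE 0.07, adjusted p = 0.00589) and HOXA4 by 0.43 (SE 0.06, adjusted p = 0.00646). Among 20 DOT1L and elongation complex partners 0 rose, 2 fell and 18 did not pass, or 1 and 2 adjusted over the list alone. As a list, camera gave adjusted p = 0.827 (adjusted p = 0.953 with an estimated correlation). The larger fall was that of AFF3, a scaffold of elongation complexes (−0.36, SE 0.06, adjusted p = 0.00869).

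**Figure D2:**
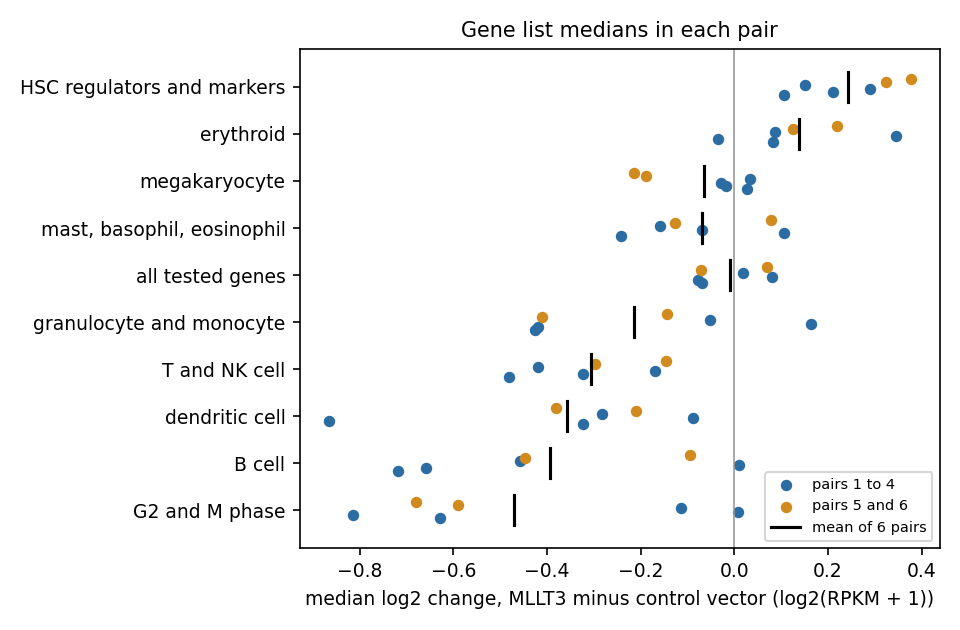
Median log2 change (MLLT3 minus control, horizontal axis) of 9 gene lists and of all tested genes in each of the 6 pairs, with pairs 1 to 4 in blue, pairs 5 and 6 in orange and a bar at the mean of the 6 pairs. The stem cell list lies above 0 in all 6 pairs, and the G2 and M list lies at 0.00721 in pair 3 and below 0 in the other 5 pairs.

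Genes of mitosis were lower. Of 24 G2 and M phase genes, 0 rose, 11 fell and 13 did not pass, or 0 and 24 adjusted over the list alone, with a median of −0.47. Camera gave adjusted p = 5.41e-16 (0.413 with an estimated correlation, 0.0839 with fry). The list median was −0.388 over pairs 1 to 4 and −0.635 over pairs 5 and 6. CENPA, the centromere histone, fell by 0.58 (SE 0.11, adjusted p = 0.0275). Among 23 S phase genes 0 rose, 1 fell and 22 did not pass, or 0 and 1 adjusted over the list alone (median −0.18). For this list camera gave adjusted p = 6.14e-05 (adjusted p = 0.599 with an estimated correlation), and the list's adjusted p was 0.0718 in pairs 1 to 4 alone. The member that fell was CLSPN, a mediator of the replication checkpoint (−0.38, SE 0.09, adjusted p = 0.0445). With 1 pair left out, the adjusted p reached 0.0741 for MKI67, 0.0905 for CENPA and 0.127 for CLSPN, and each was above 0.05 without pair 1, 2, 5 or 6. Of 12 cell cycle inhibitors and p53 targets, 0 rose and 2 fell, also adjusted over the list alone, and 10 did not pass. Tested as a set, the list had adjusted p = 0.652 by camera (adjusted p = 0.898 with an estimated correlation). The falls were in CDKN2C and in TP53INP1, a p53-induced nuclear protein (−0.45, SE 0.09, adjusted p = 0.0198, reaching 0.0687 with 1 pair left out and above 0.05 without pair 1 or 2).

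Glycolysis and hypoxia genes moved up: 7 of 20 rose, 1 fell and 12 did not pass, or 12 and 1 adjusted over the list alone (median 0.28). The list's adjusted p was 2.09e-07 by camera (adjusted p = 0.413 with an estimated correlation). PFKFB4, a regulator of glycolytic flux, rose by 0.87 (SE 0.19, adjusted p = 0.0445) and BNIP3, a hypoxia-induced mitophagy protein, by 0.73 (SE 0.16, adjusted p = 0.0480), each in 5 of 6 pairs; with 1 pair left out their adjusted p reached 0.133 and 0.145, above 0.05 without pair 2, 3, 4, 5 or 6. VEGFA, the vascular growth factor, rose by 0.60 (SE 0.10, adjusted p = 0.0127). Against the list, EGLN3, an oxygen-sensing prolyl hydroxylase, fell by 0.61 (SE 0.09, adjusted p = 0.00694). Cholesterol synthesis genes had a median of −0.15, with 0 of 18 past the threshold for a single gene, over all genes and adjusted over the list alone (camera adjusted p = 0.0066, and 0.0600 in pairs 5 and 6 alone; adjusted p = 0.599 with an estimated correlation).

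Of 10 B cell genes, 0 rose, 3 fell and 7 did not pass, or 1 and 8 adjusted over the list alone (median −0.45). Over the whole list camera gave adjusted p = 4.23e-04 (adjusted p = 0.469 with an estimated correlation), and the list's adjusted p was 0.32 in pairs 5 and 6 alone. IL7R, the interleukin-7 receptor, fell by 0.66 (SE 0.10, adjusted p = 0.00694) and CD22, a B cell receptor modulator, by 0.51 (SE 0.08, adjusted p = 0.00787). Among 9 T and NK cell genes 0 rose, 4 fell and 5 did not pass, or 0 and 6 adjusted over the list alone (median −0.29). With camera the adjusted p was 6.55e-06 (adjusted p = 0.295 with an estimated correlation). PRF1, perforin, fell by 0.61 (SE 0.06, adjusted p = 0.00102), and CD7, a surface protein of T, NK and early lymphoid cells, by 0.51 (SE 0.10, adjusted p = 0.0208, reaching 0.0681 with 1 pair left out and above 0.05 without pair 1, 2 or 5). Of 27 granulocyte and monocyte genes 1 rose, 4 fell and 22 did not pass, or 3 and 7 adjusted over the list alone (median −0.19). Camera's adjusted p was 8.47e-04 (adjusted p = 0.579 with an estimated correlation). After CSF1R the largest falls were in CD86, a costimulatory ligand (−0.53, SE 0.09, adjusted p = 0.0127), and MS4A7, a macrophage membrane protein (−0.51, SE 0.10, adjusted p = 0.0233), while CEBPA, a granulocyte transcription factor, rose by 0.38 (SE 0.07, adjusted p = 0.0241). With 1 pair left out, the adjusted p of MS4A7 reached 0.0743 (above 0.05 without pair 2, 5 or 6) and that of CEBPA 0.0681 (above 0.05 without pair 4, 5 or 6).

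The dendritic cell list held 4 measured genes, of which 0 rose, 1 fell and 3 did not pass, or 0 and 3 adjusted over the list alone (median −0.42). By camera the adjusted p was 0.0409 (adjusted p = 0.413 with an estimated correlation), and its adjusted p was 0.0809 without pair 4, 0.101 without pair 6 and 0.564 in pairs 5 and 6 alone. Its called member was CCR7, a lymph node homing receptor (−0.47, SE 0.10, adjusted p = 0.0304, and 0.0508 to 0.0786 without any 1 of pairs 1 to 6). Erythroid genes (5 measured, 1 rose, 0 fell, 4 not past, or 2 and 1 adjusted over the list alone) did not move as a list. Camera gave adjusted p = 0.455 (adjusted p = 0.599 with an estimated correlation). Nor did megakaryocyte genes (10 measured, 1 rose, 0 fell, 9 not past, or 1 and 0 adjusted over the list alone; camera adjusted p = 0.965, also with an estimated correlation). The called member of each was TRIM58, an erythroid ubiquitin ligase (0.38, SE 0.08, adjusted p = 0.0234, reaching 0.0792 with 1 pair left out and above 0.05 without pair 2, 5 or 6), and NFE2, a transcription factor of platelet and globin genes (0.46, SE 0.08, adjusted p = 0.0127). None of 5 mast cell, basophil and eosinophil genes passed, over all genes or adjusted over the list alone. Camera gave the list adjusted p = 0.780 (adjusted p = 0.898 with an estimated correlation). The same held for 12 MHC class II genes. For this list camera gave adjusted p = 0.889 (adjusted p = 0.965 with an estimated correlation). Of 6 fetal program genes 0 passed, over all genes or adjusted over the list alone. Tested as a set, the list had adjusted p = 0.780 by camera (adjusted p = 0.953 with an estimated correlation). Limma called 0 members of these 3 lists.

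Interferon-stimulated genes had a median of −0.28, with 0 of 30 rising, 5 falling and 25 not past, or 0 and 9 adjusted over the list alone. The list's adjusted p was 2.09e-07 by camera (adjusted p = 0.552 with an estimated correlation). Within pairs 5 and 6 camera's direction for this list was up (adjusted p = 0.3002). MX2, an interferon-induced GTPase, fell by 0.60 (SE 0.13, adjusted p = 0.0324) and RSAD2, viperin, by 0.52 (SE 0.10, adjusted p = 0.0227); with 1 pair left out their adjusted p reached 0.0818 (above 0.05 without any 1 of pairs 1 to 5) and 0.0623 (above 0.05 without pair 1 or 2). Of 18 immediate early genes 0 rose, 3 fell and 15 did not pass, or 1 and 7 adjusted over the list alone (median −0.10). Over the whole list camera gave adjusted p = 0.00775 (adjusted p = 0.579 with an estimated correlation). The largest change was in KLF4, a growth-arrest transcription factor (−0.52, SE 0.11, adjusted p = 0.0294, reaching 0.0938 and above 0.05 without pair 1, 2, 5 or 6). Endothelial genes, several of which stem cells share, moved up with 1 of 6 rising, 0 falling and 5 not past, or 3 and 0 adjusted over the list alone (median 0.20). With camera the adjusted p was 0.0172, and 0.0600 in pairs 5 and 6 alone (adjusted p = 0.413 with an estimated correlation). ROBO4, a receptor of endothelium and stem cells, rose by 0.56 (SE 0.09, adjusted p = 0.0130). Small noncoding and nuclear RNAs moved up with 2 of 8 rising, 0 falling and 6 not past, or 3 and 0 adjusted over the list alone (median 0.17). Camera's adjusted p was 0.00282 (adjusted p = 0.410 with an estimated correlation). The rises were in GAS5, a host of small nucleolar RNAs (0.47, SE 0.08, adjusted p = 0.0137, and 0.0503 without pair 2), and TERC, the telomerase RNA (0.37, SE 0.08, adjusted p = 0.0268, reaching 0.0713 and above 0.05 without pair 1, 5 or 6).

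The lists of stromal genes (6 measured, 1 rose, 0 fell, 5 not past, or 1 and 2 adjusted over the list alone; camera adjusted p = 0.652; adjusted p = 0.898 with an estimated correlation) and of inflammatory and NF-kB genes (14 measured, 1 rose, 0 fell, 13 not past, or 1 and 1 adjusted over the list alone; camera adjusted p = 0.652; adjusted p = 0.898 with an estimated correlation) did not move as lists. COL5A1, a fibrillar collagen chain, rose in the former (0.56, SE 0.06, adjusted p = 0.00102) and IL1B in the latter. Neither did heat shock genes (14 measured, 1 rose, 0 fell, 13 not past, with the same counts adjusted over the list alone; camera adjusted p = 0.481; adjusted p = 0.898 with an estimated correlation) or homing and niche receptor genes (20 measured, 0 rose, 2 fell, 18 not past, or 1 and 4 adjusted over the list alone; camera adjusted p = 0.751; adjusted p = 0.898 with an estimated correlation). Their called members included HSPB1, a small heat shock protein (0.39, SE 0.08, adjusted p = 0.0304, reaching 0.101 and above 0.05 without pair 1, 4, 5 or 6), and IL6R, the interleukin-6 receptor (−0.54, SE 0.09, adjusted p = 0.0124). Hepatocyte genes were not tested, since 0 of 18 reached the filter. For the fetal program list the mean (0.02) differed in sign from the median (−0.04) and camera's direction.

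Counts of called genes depended on the pairing and on each pair: without the block 17 genes rose and 28 fell. In pairs 1 to 4 alone 40 rose and 64 fell, and in pairs 5 and 6 alone 340 rose and 400 fell. Leaving out pair 1 gave 211 rises and 104 falls, pair 2 gave 99 and 67, pair 4 gave 149 and 196, pair 5 gave 121 and 95, and pair 6 gave 86 and 107, against 230 and 437 without pair 3. Of 54 called genes considered for naming, 41 did not pass without the block, 28 of 53 tested did not in pairs 1 to 4 alone and 12 of 49 tested did not in pairs 5 and 6 alone. Without the block the lists of granulocyte and monocyte genes (adjusted p = 0.0877), dendritic cell genes (adjusted p = 0.1195) and immediate early genes (adjusted p = 0.546) did not pass. After median centring (adjusted p = 0.0506) or TMM factors (adjusted p = 0.0515) the dendritic cell list did not pass, and after quantile normalization neither it nor the small noncoding RNA list did (adjusted p = 0.0669 each). With a filter of RPKM 5 the lists of granulocyte and monocyte genes (adjusted p = 0.0972), dendritic cell genes (adjusted p = 0.7469) and endothelial genes (adjusted p = 0.1201) did not pass, and with no filter the latter 2 did not (adjusted p = 0.1207 and 0.4147).

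Culture for 4 weeks with the control vector was followed by larger changes. JCHAIN, the immunoglobulin joining chain of lymphoid cells, rose from 2.94 ± 1.33 RPKM (SD, n = 3) to 149 ± 33.2 RPKM (SD, n = 6), a log2 change of 5.28 (SE 0.22, adjusted p = 1.09e-10). IL7R rose from 0.821 to 62.0 RPKM (log2 change 5.08, SE 0.29, adjusted p = 4.49e-09). In the other direction PRG2, the eosinophil major basic protein, fell from 80.3 ± 36.1 RPKM to 0.957 ± 0.561 RPKM (log2 change −5.34, SE 0.28, adjusted p = 2.34e-09), and MDK, the growth factor midkine, from 84.7 to 1.47 RPKM (log2 change −5.10, SE 0.21, adjusted p = 1.09e-10). Of 13022 genes tested, 1635 rose and 4000 fell, and for 4517 of these 5635 the groups did not overlap.

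The median of all genes itself shifted by −0.13 on the log2 scale, beside the lower exonic share of the cultured libraries, and after median centring 2498 genes rose and 2625 fell, 48.8% of calls rising against 29.0% before. List medians below are given relative to the median of all genes. Leaving out uncultured sample 1 gave 1302 rises and 2568 falls, and leaving out uncultured sample 2 gave 1402 and 2664. With only the libraries named like the uncultured ones (pairs 5 and 6 among controls), 879 genes rose and 1690 fell.

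Further large rises in control culture were in KIAA0087 (log2 change 4.21, SE 0.12, adjusted p = 4.63e-12, 0.504 to 26.9 RPKM), SH3BP5, an adaptor that inhibits BTK (3.40, SE 0.12, adjusted p = 2.78e-11), LPAR3, a lysophosphatidic acid receptor (3.36, SE 0.22, adjusted p = 2.08e-08), and PACSIN1, a protein of membrane trafficking (3.33, SE 0.17, adjusted p = 2.11e-09). IFITM1, an interferon-induced membrane protein, rose by 3.29 (SE 0.17, adjusted p = 2.00e-09) and CD22 by 3.18 (SE 0.10, adjusted p = 7.77e-12). Further large falls were in DLK1, a fetal growth regulator of the Notch ligand family (−4.42, SE 0.24, adjusted p = 3.26e-09), JUN, a subunit of the AP-1 transcription factor (−4.32, SE 0.58, adjusted p = 2.93e-05), and CLC, the eosinophil and basophil galectin (−4.30, SE 0.36, adjusted p = 2.47e-07). CNRIP1, a cannabinoid receptor interacting protein, decreased by 3.88 (SE 0.24, adjusted p = 1.14e-08), and TERC from 82.3 to 5.45 RPKM (−3.798, SE 0.41, adjusted p = 2.69e-06).

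Genes of the eosinophil, red cell, platelet and endothelial lineages were lower after control culture. Of 9 mast cell, basophil and eosinophil genes 0 rose, 8 fell and 1 did not pass, with the same counts adjusted over the list alone (relative median −2.44). By camera the adjusted p was 1.73e-05 (0.189 with an estimated correlation). After PRG2 and CLC, CPA3, the mast cell carboxypeptidase, had the largest fall, from 13.4 to 0.833 RPKM (log2 change −2.99, SE 0.25). Of 16 erythroid genes 1 rose, 14 fell and 1 did not pass, or 2 and 14 adjusted over the list alone (relative median −1.69). As a list, camera gave adjusted p = 5.61e-06 (0.224 with an estimated correlation). KLF1, a master regulator of globin genes, fell from 15.6 to 0.308 RPKM (log2 change −3.61, SE 0.23, adjusted p = 1.52e-08) and GATA1, an erythroid and megakaryocyte transcription factor, from 16.3 to 0.521 RPKM (−3.45, SE 0.36, adjusted p = 1.80e-06). Megakaryocyte genes (16 measured) included 2 that rose, 9 that fell and 5 that did not pass, the same adjusted over the list alone (relative median −0.58). Camera gave the list adjusted p = 0.0142 (0.486 with an estimated correlation). GP1BB, a platelet adhesion receptor chain, fell by 3.02 (SE 0.24, adjusted p = 1.24e-07) as did CLEC1B, a platelet lectin receptor (−1.97, SE 0.26, adjusted p = 2.05e-05). Of 12 endothelial genes 1 rose, 9 fell and 2 did not pass, with the same counts adjusted over the list alone (relative median −1.26). For this list camera gave adjusted p = 0.00102 (0.189 with an estimated correlation). OIT3, a gene of liver sinusoidal endothelium, was listed at 0 in all 12 cultured samples and at 6.37 ± 2.94 RPKM (SD, n = 3) in uncultured ones. Without 1 uncultured sample the megakaryocyte and endothelial lists did not pass (adjusted p = 0.207 to 0.251 and 0.251 to 0.545). With the tested genes kept, chosen after seeing the data and with the left-out sample, both did (at most 0.0163 and 0.00292). With a filter of RPKM 5 neither passed (0.0777 and 0.9055), and with no filter the megakaryocyte list did not (0.0868).

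Among 39 HSC regulators and surface markers 7 rose, 18 fell and 14 did not pass, the same adjusted over the list alone (relative median −0.26). This list had adjusted p = 0.136 by camera (0.624 with an estimated correlation) and 4.16e-05 (down) by fry. ZBTB16, a zinc finger repressor of stem and lymphoid cells, fell by 3.44 (SE 0.37, adjusted p = 2.61e-06), GATA2, a stem cell transcription factor, by 2.04 (SE 0.17, adjusted p = 1.98e-07), TEK, the angiopoietin receptor TIE2, by 2.02 (SE 0.12, adjusted p = 7.53e-09), and KIT followed (−1.98, SE 0.28, adjusted p = 4.78e-05). HOXA and HOXB cluster genes split: 9 of 12 rose and 3 fell, the same adjusted over the list alone (relative median 0.95). The list's adjusted p was 5.64e-04 by camera (adjusted p = 0.189 with an estimated correlation). HOXA9 rose by 1.65 (SE 0.09, adjusted p = 3.42e-09), while HOXB3 fell by 1.45 (SE 0.11, adjusted p = 1.00e-07) and HOXB2 by 1.37 (SE 0.24, adjusted p = 3.40e-04). Of 10 fetal program genes 1 rose, 7 fell and 2 did not pass, the same adjusted over the list alone (relative median −1.19). Over the list camera gave adjusted p = 0.0085 (0.208 with an estimated correlation). The adjusted p was 0.0958 to 0.110 without uncultured sample 1 or 2. It was at most 0.00336 with the tested genes kept and 0.0628 with a filter of RPKM 5. After DLK1 the largest fall was in the imprinted noncoding RNA H19 (−3.54, SE 0.38, adjusted p = 2.59e-06). Among 20 DOT1L and elongation complex partners 4 rose, 5 fell and 11 did not pass, the same adjusted over the list alone, or 5 and 2 after median centring. With camera the adjusted p was 0.430 (adjusted p = 0.720 with an estimated correlation). AFF1, an elongation complex scaffold, rose by 0.80 (SE 0.10, adjusted p = 1.57e-05).

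B cell genes moved up in control culture: 6 of 11 rose, 1 fell and 4 did not pass, the same adjusted over the list alone (relative median 0.60). Camera's adjusted p was 5.72e-04 (adjusted p = 0.189 with an estimated correlation). After IL7R and CD22, the largest change was against the list, in IGLL1, the surrogate light chain of pre-B cells (−2.47, SE 0.41, adjusted p = 1.96e-04). Of 10 T and NK cell genes 5 rose, 2 fell and 3 did not pass, or 7 and 2 adjusted over the list alone (relative median 1.19). By camera the adjusted p was 0.00102 (adjusted p = 0.0809 with an estimated correlation). PRF1 rose by 3.09 (SE 0.34, adjusted p = 3.75e-06) and CD3E, a T cell receptor chain, by 2.16 (SE 0.19, adjusted p = 3.29e-07), while GATA3, a T cell transcription factor also active in stem cells, fell by 1.63 (SE 0.16, adjusted p = 1.53e-06). Granulocyte and monocyte genes went both ways, with 5 of 29 rising, 4 falling and 20 not past, the same adjusted over the list alone (camera adjusted p = 0.279; adjusted p = 0.741 with an estimated correlation): CSF3R, the G-CSF receptor, fell by 2.32 (SE 0.34, adjusted p = 5.67e-05) and RNASE3, the eosinophil cationic protein, by 1.84 (SE 0.32, adjusted p = 3.10e-04), while ITGAM, the integrin CD11b, rose by 1.59 (SE 0.24, adjusted p = 7.89e-05). Dendritic cell genes (5 measured) included 3 that rose and 1 that fell, with 1 not past, or 3 and 2 adjusted over the list alone, and 3 and 0 after median centring. As a list, camera gave adjusted p = 0.183 (adjusted p = 0.406 with an estimated correlation). The largest change was in CCR7 (1.64, SE 0.27, adjusted p = 1.65e-04). Of 12 MHC class II genes 2 rose, 0 fell and 10 did not pass, or 0 and 0 adjusted over the list alone, and 4 and 0 after median centring. Camera gave the list adjusted p = 0.112 (adjusted p = 0.703 with an estimated correlation). HLA-DMB, a peptide-loading chaperone chain, rose by 0.58 (SE 0.18, adjusted p = 0.0168, but 0.106 without uncultured sample 1).

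Cholesterol synthesis genes rose together in control culture, 14 of 18 with 0 falling and 4 not past, the same adjusted over the list alone (relative median 0.76). For this list camera gave adjusted p = 2.45e-09 (adjusted p = 0.189 with an estimated correlation). STARD4, a sterol carrier, rose by 0.94 (SE 0.14, adjusted p = 5.46e-05). Of 20 glycolysis and hypoxia genes 15 rose, 1 fell and 4 did not pass, the same adjusted over the list alone (relative median 1.06). Tested as a set, the list had adjusted p = 1.07e-09 by camera (adjusted p = 0.189 with an estimated correlation), with ALDOC, an aldolase, up by 2.51 (SE 0.18, adjusted p = 5.30e-08), SLC2A3, a glucose transporter, by 2.14 (SE 0.35, adjusted p = 1.86e-04) and BNIP3 by 2.14 (SE 0.37, adjusted p = 3.17e-04). Of 20 immediate early genes 1 rose, 13 fell and 6 did not pass, or 1 and 14 adjusted over the list alone (relative median −0.99). The list's adjusted p was 0.0142 by camera (adjusted p = 0.624 with an estimated correlation), and the list's adjusted p was 0.202 without uncultured sample 3 and 0.0688 with a filter of RPKM 5. Next to JUN, FOS, another AP-1 subunit, fell by 2.81 (SE 0.78, adjusted p = 0.00906, but 0.0562 without uncultured sample 3, or 0.0498 with the tested genes kept). Of 14 heat shock genes 1 rose, 11 fell and 2 did not pass, the same adjusted over the list alone (relative median −0.53). Over the whole list camera gave adjusted p = 0.0107 (adjusted p = 0.486 with an estimated correlation), with HSPB1 down from 61.0 to 12.8 RPKM (−2.17, SE 0.21, adjusted p = 1.04e-06). Immediate early and heat shock genes are known to respond to the handling of cells.

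Interferon-stimulated genes moved up in control culture, with 12 of 30 rising, 4 falling and 14 not past, or 13 and 5 adjusted over the list alone, and 14 and 1 after median centring (relative median 0.32). With camera the adjusted p was 0.00102 (adjusted p = 0.624 with an estimated correlation). After IFITM1 came IFI44L (1.44, SE 0.48, adjusted p = 0.0234) and IFI6 (1.32, SE 0.41, adjusted p = 0.0161), while IFITM3, an antiviral membrane protein, fell by 1.23 (SE 0.16, adjusted p = 2.12e-05). The adjusted p of IFI44L ran from 0.0523 to 0.0744 without any 1 of uncultured samples 1 to 3, and that of IFI6 was 0.0524 to 0.0683 without uncultured sample 1 or 2. With the series of names as a term the adjusted p was 0.0771 for IFI44L and 0.0886 for IFI6, with a block by library code number 0.0607 and 0.0614, and with voom 0.0582 for IFI44L. Of 16 inflammatory and NF-kB genes 3 rose, 9 fell and 4 did not pass, or 4 and 9 adjusted over the list alone, and 4 and 6 after median centring. Camera's adjusted p was 0.586 (adjusted p = 0.724 with an estimated correlation). IL1B fell from 43.4 to 4.35 RPKM (−3.14, SE 0.37, adjusted p = 7.21e-06) and TRAF1, a TNF receptor adaptor, rose by 1.73 (SE 0.20, adjusted p = 6.32e-06). Homing and niche receptor genes went both ways, with 6 of 21 rising, 6 falling and 9 not past, the same adjusted over the list alone (camera adjusted p = 0.531; adjusted p = 0.724 with an estimated correlation): CSF2RB, the common beta chain of cytokine receptors, fell by 1.95 (SE 0.20, adjusted p = 1.43e-06).

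Cell cycle genes moved little in control culture. Of 24 G2 and M phase genes 0 rose, 3 fell and 21 did not pass, or 0 and 2 adjusted over the list alone. By camera the adjusted p was 0.251 (adjusted p = 0.772 with an estimated correlation). Of 23 S phase genes 0 rose, 2 fell and 21 did not pass, the same adjusted over the list alone. As a list, camera gave adjusted p = 0.553 (adjusted p = 0.873 with an estimated correlation). UBE2C, a mitotic ubiquitin-conjugating enzyme, fell by 0.80 (SE 0.15, adjusted p = 5.41e-04) and UHRF1, a cofactor of maintenance methylation, by 0.90 (SE 0.22, adjusted p = 0.00391, but 0.0936 with only the libraries named like the uncultured ones and 0.0764 with a block by library code number). Among 13 cell cycle inhibitors and p53 targets 3 rose, 4 fell and 6 did not pass, or 4 and 5 adjusted over the list alone, and 5 and 3 after median centring. Camera gave the list adjusted p = 0.279 (adjusted p = 0.624 with an estimated correlation), and CDKN2C rose by 1.11 (SE 0.20, adjusted p = 4.82e-04). Of 8 stromal genes 1 rose, 5 fell and 2 did not pass, the same adjusted over the list alone. For this list camera gave adjusted p = 0.279 (adjusted p = 0.712 with an estimated correlation). COL1A1, a fibrillar collagen chain, was at 20.1 ± 31.3 RPKM (SD, n = 3) in uncultured samples, a spread wider than the mean, and fell by 2.68 (SE 0.65, adjusted p = 0.00375, but 0.1515 with only the libraries named like the uncultured ones). Of 8 small noncoding and nuclear RNAs 2 rose, 1 fell and 5 did not pass, or 3 and 1 adjusted over the list alone. Tested as a set, the list had adjusted p = 0.279 by camera (adjusted p = 0.624 with an estimated correlation). Beside TERC, which fell, RPPH1, the RNA of RNase P, rose by 1.41 (SE 0.19, adjusted p = 2.98e-05). Hepatocyte genes again had 0 of 18 measured. Median, mean and camera's direction differed in sign for the lists of DOT1L partners, granulocyte and monocyte genes, MHC class II genes, cell cycle inhibitors, homing genes and small noncoding RNAs.

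**Figure D3:**
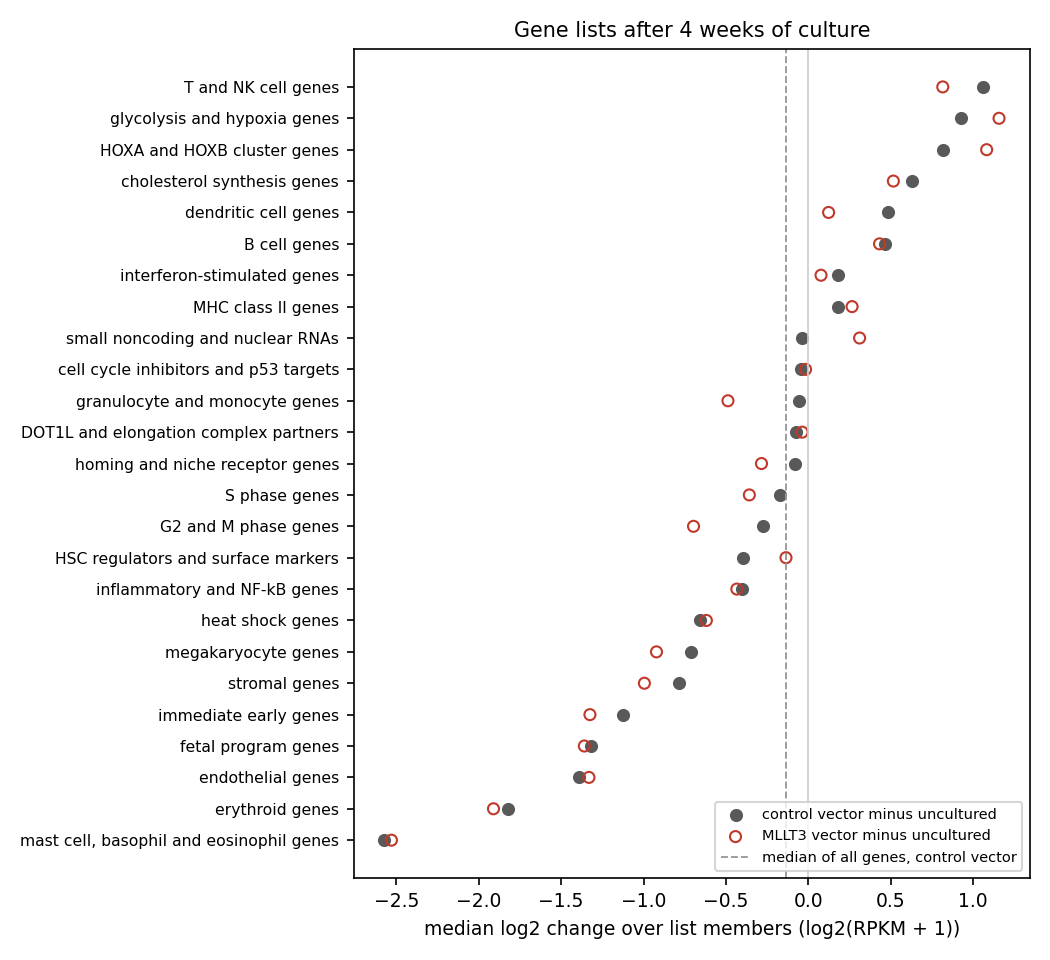
Median log2 change from uncultured cells (horizontal axis) of 25 gene lists in control culture (filled points) and in MLLT3 culture (open points), with a dashed line at the median of all genes in control culture, −0.13. Mast cell, basophil and eosinophil genes lie lowest, at −2.57 and −2.53.

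Set against uncultured cells, KIAA0087 in the MLLT3 group rose by 5.26 (SE 0.12, n = 6 against 3, adjusted p = 1.45e-13, limma), JCHAIN by 4.68 (SE 0.22, adjusted p = 6.47e-10) and IL7R by 4.42 (SE 0.29, adjusted p = 1.76e-08). PRG2 fell by 5.46 (SE 0.28, adjusted p = 2.05e-09), MDK by 4.79 (SE 0.21, adjusted p = 3.75e-10) and JUN by 4.55 (SE 0.58, adjusted p = 1.90e-05). Mitotic genes were lower here as well: 24 of 24 G2 and M phase genes fell. Of 13022 genes tested, 1628 rose and 4270 fell, and for 4593 of these 5898 the groups did not overlap. The median of all genes was −0.14, and after median centring 2514 rose and 2861 fell, 46.8% of calls rising against 27.6% before. With only the libraries named like the uncultured ones (pairs 5 and 6 among MLLT3 samples), 1152 rose and 2215 fell.

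Further rises were in LPAR3 (3.62, SE 0.22, adjusted p = 1.15e-08), SH3BP5 (3.19, SE 0.12, adjusted p = 8.68e-11), IGFBP2 (3.18, SE 0.26, adjusted p = 1.93e-07), PPFIA4, a liprin scaffold (3.16, SE 0.18, adjusted p = 5.65e-09), and ALDOC (3.10, SE 0.18, adjusted p = 6.17e-09). Further falls were in DLK1 (−4.32, SE 0.24, adjusted p = 4.85e-09), CLC (−4.18, SE 0.36, adjusted p = 3.68e-07) and CNRIP1 (−3.85, SE 0.24, adjusted p = 1.38e-08). FAM178B decreased by 3.71 (SE 0.22, adjusted p = 8.07e-09) as did KLF1 (−3.515, SE 0.23, adjusted p = 2.21e-08).

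The G2 and M phase list, with 0 rising, 24 falling and 0 not past, the same adjusted over the list alone, had a median of −0.56 relative to all genes. The list's adjusted p was 6.14e-06 by camera (adjusted p = 0.457 with an estimated correlation). The largest change was in UBE2C (−1.14, SE 0.15, adjusted p = 2.43e-05) and BIRC5, survivin (−0.95, SE 0.17, adjusted p = 4.09e-04). Of 23 S phase genes 0 rose, 12 fell and 11 did not pass, or 0 and 14 adjusted over the list alone. Over the whole list camera gave adjusted p = 0.0332 (adjusted p = 0.731 with an estimated correlation), with 8 falling after median centring, and UHRF1 fell by 1.12 (SE 0.22, adjusted p = 7.74e-04). The S phase list's adjusted p reached 0.1075 and was above 0.05 without uncultured sample 1 or 2 or MLLT3 sample 2 or 5, and it was 0.0534 with a filter of RPKM 5, 0.2975 with a block by library code number and 0.1159 with the series of names as a term. Of 39 HSC regulators and surface markers 9 rose, 14 fell and 16 did not pass, or 10 and 15 adjusted over the list alone (relative median 0.00). Adjusted p was 0.843 by camera (0.927 with an estimated correlation) and 0.00433 (down) by fry. ZBTB16 fell by 3.21 (SE 0.37, adjusted p = 5.84e-06), TEK by 2.12 (SE 0.12, adjusted p = 5.65e-09) and GATA2 followed (−1.82, SE 0.17, adjusted p = 6.56e-07), while RBPMS, an RNA-binding protein, rose by 1.79 (SE 0.15, adjusted p = 3.43e-07). HOXA and HOXB cluster genes again had 9 of 12 rising and 3 falling, the same adjusted over the list alone (relative median 1.22). Camera's adjusted p was 1.91e-05 (adjusted p = 0.176 with an estimated correlation), with HOXA6 up by 1.47 (SE 0.14, adjusted p = 9.11e-07) and HOXA9 by 1.42 (SE 0.09, adjusted p = 1.61e-08).

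Genes of the eosinophil and red cell lineages were lower with MLLT3 than in uncultured cells. Mast cell, basophil and eosinophil genes (9 measured, 0 rose, 8 fell, 1 not past; camera adjusted p = 2.53e-05; adjusted p = 0.252 with an estimated correlation) and erythroid genes (16 measured, 0 rose, 14 fell, 2 not past; camera adjusted p = 7.46e-06; adjusted p = 0.271 with an estimated correlation) had relative medians of −2.39 and −1.77. Adjusted over the list alone, 0 rose and 8 fell in the former and 2 rose and 14 fell in the latter. Megakaryocyte genes (16 measured, 1 rose, 10 fell, 5 not past, or 1 and 11 adjusted over the list alone; camera adjusted p = 0.0112; 0.457 with an estimated correlation) and endothelial genes (12 measured, 1 rose, 7 fell, 4 not past, or 1 and 8 adjusted over the list alone; camera adjusted p = 0.00425; 0.252 with an estimated correlation) were lower too. Without 1 uncultured sample their adjusted p was 0.151 to 0.252 and 0.471 to 0.782. With the tested genes kept it was at most 0.0115 and 0.01003. With a filter of RPKM 5 the megakaryocyte list did not pass (0.1397) and camera's direction for the endothelial list was up (0.8752). The fetal program list (10 measured, 1 rose, 8 fell, 1 not past, the same adjusted over the list alone; camera adjusted p = 0.00728; 0.252 with an estimated correlation) fell as well. Of 11 B cell genes 5 rose, 3 fell and 3 did not pass, or 5 and 4 adjusted over the list alone (relative median 0.57). By camera the adjusted p was 0.0167 (adjusted p = 0.382 with an estimated correlation). Of 10 T and NK cell genes 5 rose, 2 fell and 3 did not pass, the same adjusted over the list alone (relative median 0.96). As a list, camera gave adjusted p = 0.00849 (adjusted p = 0.176 with an estimated correlation). After median centring neither the B cell list nor the T and NK cell list passed (adjusted p = 0.0688 each); with quantile normalization their adjusted p was 0.0809 and 0.0865, with TMM factors 0.1038 and 0.1096, and that of the B cell list 0.0753 with no filter. Granulocyte and monocyte genes (29 measured, 4 rose, 7 fell, 18 not past, or 4 and 5 adjusted over the list alone; camera adjusted p = 0.653; 0.908 with an estimated correlation), dendritic cell genes (5 measured, 1 rose, 0 fell, 4 not past, the same adjusted over the list alone; camera adjusted p = 0.267; 0.457 with an estimated correlation), MHC class II genes (12 measured, 0 rose, 1 fell, 11 not past, or 0 and 0 adjusted over the list alone, and 4 and 0 after median centring; camera adjusted p = 0.0773; 0.731 with an estimated correlation) and stromal genes (8 measured, 1 rose, 5 fell, 2 not past, the same adjusted over the list alone; camera adjusted p = 0.267; 0.731 with an estimated correlation, 0.00689 and down with fry) were not called by camera.

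Glycolysis and hypoxia genes were higher with 16 of 20 rising, 0 falling and 4 not past, or 17 and 0 adjusted over the list alone (relative median 1.30). Camera gave the list adjusted p = 1.21e-12 (adjusted p = 0.176 with an estimated correlation). After ALDOC the largest rise was in BNIP3 (2.86, SE 0.37, adjusted p = 2.21e-05). Of 18 cholesterol synthesis genes 11 rose, 0 fell and 7 did not pass, the same adjusted over the list alone (relative median 0.66). For this list camera gave adjusted p = 5.96e-07 (adjusted p = 0.271 with an estimated correlation). Immediate early genes (20 measured, 0 rose, 13 fell, 7 not past, or 1 and 14 adjusted over the list alone; camera adjusted p = 0.00849, and 0.111 without uncultured sample 3; adjusted p = 0.572 with an estimated correlation) and heat shock genes (14 measured, 1 rose, 11 fell, 2 not past, the same adjusted over the list alone; camera adjusted p = 0.0151; adjusted p = 0.457 with an estimated correlation) were lower. Small noncoding and nuclear RNAs were higher as a list (8 measured, 2 rose, 1 fell, 5 not past, or 5 and 1 adjusted over the list alone and also after median centring; camera adjusted p = 0.0326, reaching 0.0656 and above 0.05 without uncultured sample 1 or 2 or MLLT3 sample 2, or without uncultured sample 2 with the tested genes kept; adjusted p = 0.382 with an estimated correlation). This list did not pass after median centring (adjusted p = 0.0699), quantile normalization (adjusted p = 0.0809) or TMM factors (adjusted p = 0.0747), nor with no filter (0.0515), a block by library code number (0.0775), the series of names as a term (0.174) or only the libraries named like the uncultured ones (0.0656). Interferon-stimulated genes (30 measured, 3 rose, 6 fell, 21 not past, the same adjusted over the list alone, and 4 and 4 after median centring; camera adjusted p = 0.169; adjusted p = 0.760 with an estimated correlation), inflammatory and NF-kB genes (16 measured, 2 rose, 8 fell, 6 not past, the same adjusted over the list alone; camera adjusted p = 0.630; adjusted p = 0.731 with an estimated correlation), DOT1L and elongation complex partners (20 measured, 2 rose, 4 fell, 14 not past, the same adjusted over the list alone, and 4 and 3 after median centring; camera adjusted p = 0.511; adjusted p = 0.731 with an estimated correlation), cell cycle inhibitors and p53 targets (13 measured, 3 rose, 3 fell, 7 not past, the same adjusted over the list alone; camera adjusted p = 0.511; adjusted p = 0.731 with an estimated correlation) and homing and niche receptor genes (21 measured, 7 rose, 8 fell, 6 not past, the same adjusted over the list alone; camera adjusted p = 0.630; adjusted p = 0.767 with an estimated correlation) did not move as lists. Median and camera's direction differed in sign for the lists of HSC regulators, DOT1L partners, granulocyte and monocyte genes, cell cycle inhibitors and homing genes, and the mean and camera's direction for MHC class II genes. Leaving out uncultured sample 1 gave 1309 rises and 2885 falls in this comparison, and leaving out uncultured sample 2 gave 1408 and 2955, against 1365 and 4069 without uncultured sample 3.

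Genes lowered by culture and raised by MLLT3, and the reverse, were then counted among the 12558 genes tested in both comparisons. AVP fell from 2.82 RPKM uncultured to 0.607 RPKM in control culture and stood at 2.36 RPKM with MLLT3. SKAP1 stood at 5.71, 2.10 and 4.62 RPKM, and IL1B at 43.4, 4.35 and 8.96 RPKM, in the same order. In the opposite direction CYBB rose from 3.76 to 39.7 RPKM in control culture and stood at 13.9 RPKM with MLLT3, and RPS6KA2 stood at 1.10, 9.02 and 3.83 RPKM. ABCA9-AS1, a noncoding antisense gene, was listed at 0 in the uncultured samples and stood at 11.9 RPKM in control culture and 2.78 RPKM with MLLT3. In all, 126 genes fell in culture and rose with MLLT3, where independent lists would share 87.6, and 137 rose in culture and fell with MLLT3, against 39.3. By comparison 59 rose in both (39.5 for independent lists) and 36 fell in both (87.3). With the 6 controls split 3 and 3, so that no control entered both comparisons, the median counts over 20 splits were 15.5 for fell and rose (range 0 to 102, 8.23 for independent lists) and 21 for rose and fell (range 1 to 108, 2.97 for independent lists). The same splits gave a median of 16 for rose in both (range 0 to 55, 4.66 for independent lists) and 1 for fell in both (range 0 to 243, 6.02 for independent lists). Across genes, which are not independent replicates, the covariance of the 2 sets of log2 changes was −0.0191 against −0.00603 simulated, a difference of −0.0130, and −0.0128 as the median over split controls; the correlation was −0.21 against −0.31 simulated and −0.13 over split controls.

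Over all genes that fell in control culture, MLLT3 samples were not measurably nearer to the uncultured level. The median level of these genes in MLLT3 samples minus paired controls averaged 0.0089 on the log2 scale (SD 0.083, n = 6 pairs), was higher in 3 of 6 pairs and gave p = 0.812 in the exact two-sided sign-flip permutation test, whose smallest possible p was 0.0312. Relative to the median of all genes, a setting outside the fixed design, the mean was 0.017, higher in 5 of 6 pairs (exact p = 0.0625). Without pair 3, 4 or 6 the mean was −0.011, −4.76e-04 or −0.0059. For genes that rose in control culture the mean difference was −0.043 (exact p = 0.250, n = 6 pairs).

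The authors' deposited table, a paired edgeR comparison of the same 12 cultured samples, holds 929 genes up and 1051 down at an adjusted p under 0.05. Its heading names control before MLLT3, and its direction, MLLT3 over control, was inferred from the levels of the samples. Read this way, in the authors' deposited table MLLT3 has a log2 fold change of 1.47, AVP 1.89, KIAA0087 1.09, PROM1 0.91, HLF 0.79, CYBB −1.55 and CSF1R −1.19. Of the 303 genes that rose in the limma fit, 292 are also up in the authors' deposited table, and 294 of the 302 that fell are also down, with 0 called in opposite directions at an adjusted p under 0.05 in each. Across the 12558 genes the log2 changes of the limma fit and of the authors' deposited table correlated at 0.943, over genes that are not independent replicates.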

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

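In this part, the tests on scaling, on blood lineages, on the exonic share, on hepatocyte genes and on lymphoid genes, and the G2 and M phase tests, were chosen only after the result was seen; the stem cell test within pairs 1 to 4 and the sample splits were chosen before.

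Stem cell genes were higher with MLLT3, and 3 technical explanations were tested against an effect of the vector. If the rise came only from the other series of library names (pairs 5 and 6), the list median over pairs 1 to 4 would lie at 0; it was 0.189 (SE 0.040). If it came from a different exonic share of tags, the list would follow the median of all genes; it lay 0.251 above that median (SE 0.040, n = 6 pairs). If MLLT3 libraries held fewer cells of all other blood lineages alike, 7 lineage lists would fall together; the gap between the highest list (erythroid, 0.14) and the lowest (B cell, −0.39) was 0.532, above the 95th percentile of 0.401 over 10000 within-pair permutations (median 0.269, permutation p = 5.00e-04). The lists differed, but equal loss need not lower them equally. With 6 of 7 below 0, loss of all or some lineages remains open.

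Genes of G2 and M phase were lower with MLLT3, and 2 technical explanations were tested. Over pairs 1 to 4 the list median was −0.388 with an SE of 0.198, −0.376 with an SE of 0.162 relative to the median of all genes, and −0.635 over pairs 5 and 6. Per pair the medians were −0.63, −0.81, 0.00721, −0.11, −0.59 and −0.68, so 2 of pairs 1 to 4 fell as far as pairs 5 and 6. In pairs 1 to 4 alone camera called the list (adjusted p = 4.99e-11), but not with its genes' estimated correlation of 0.954 (0.537). The raw mean was under 2 SE from 0, the relative one over, so a part of pairs 5 and 6 in the fall remains open. A different exonic share of tags does not account for the fall, since the list lay −0.462 from the median of all genes (SE 0.120, n = 6 pairs).

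After control culture more genes fell than rose, among them eosinophil, erythroid, endothelial and stromal genes. The median change of all genes lay 0.00656 from the log2 ratio of exonic shares (−0.14, SE 0.0508), so the surplus of falls could come from a lower exonic share; this match is partly built in, because RPKM is scaled to all tags. RNA of all liver cells carried into the uncultured libraries would bring hepatocyte RNA, but the highest median of 18 hepatocyte genes in an uncultured library was 0.073 RPKM, with ALB highest at 0.879 RPKM. A lower share of all other cell types after culture would lower lymphoid genes too. B and T and NK cell genes lay 0.931 above the median of all genes (SE 0.056 over n = 6 controls). A rise within HSPC could hide a loss, so this stays open. Which of sorting, culture or stroma changed the eosinophil, erythroid and endothelial genes was not tested.

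Chance splits of the samples were tried for each comparison. Among 32 within-pair swaps of MLLT3 and control only 1, the real one, called 605 genes, and the highest other called 1. Among 84 splits of 3 and 6 for control against uncultured only 1, the real one, called 5635 genes, and the highest other called 3. For MLLT3 against uncultured only 1 of 84 called 5898, and the highest other called 2.

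Single samples far from the other 5 of their group appeared in 14 of 230 groups of 6 named-gene values, where chance gives about 1 in 20; the value is the gap to the nearest sample over the range, both on log2(RPKM + 1), compared with Dixon's limit. Among controls, ABCA9-AS1 gave 0.676 in sample 4 (20.2 RPKM against 8.69 to 11.5), IFITM1 0.688 in sample 3 (107.6 RPKM against 65.0 to 76.1), and ITGAM 0.742 in sample 4 (20.9 RPKM against 9.54 to 11.7). IFI44L gave 0.649 in control 3 (14.8 RPKM against 1.25 to 3.45) and KLF1 0.715 in control 5 (0.948 RPKM against 0.086 to 0.283). In control 5 both FAM178B (0.081 RPKM) and STAB2 (0.013 RPKM) had a gap of 1, being listed at 0 in the other 5. With MLLT3, AVP gave 0.640 in sample 3 (1.72 RPKM against 2.25 to 2.59), PRSS3P2 0.660 in sample 1 (4.25 RPKM against 7.14 to 9.20) and CCR7 0.677 in sample 4 (4.41 RPKM against 1.08 to 1.84). TEK gave 0.726 in MLLT3 sample 6 (0 RPKM against 0.104 to 0.146) and GATA1 0.653 in MLLT3 sample 5 (2.51 RPKM against 0.095 to 0.641). STAB2 in MLLT3 sample 6 (0.005 RPKM) and KDR in MLLT3 sample 2 (0.011 RPKM) had a gap of 1, with the other 5 listed at 0.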

How the results depend on the processing

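No test in this part bears on an explanation chosen only after the result was seen; the fits to rebuilt reads and those without 1 uncultured sample with the tested genes kept were chosen after the data were seen and all other settings before. Where a value differs below, the cause was not tested unless the setting itself shows it.

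For MLLT3 against control, 303 genes rose and 302 fell, and both counts stayed within 1.5 times with pseudocounts of 0.1 and 0.5, a filter of RPKM 5, limma without trend and robust settings and the pair as a random effect. Other settings gave, for genes that rose and fell, 579 and 479 (median centring), 598 and 592 (quantile normalization), 632 and 494 (TMM factors), 61 and 59 (no filter on low values) and 3 and 5 (fold of at least 2, a stricter limit by construction). Rebuilt reads gave 876 and 915 (edgeR), 860 and 928 (edgeR with DESeq2 size factors), 984 and 1097 (edgeR, no filter), 806 and 918 (DESeq2) and 974 and 1082 (voom). Pairs 1 to 4 alone gave 40 and 64, with fewer samples, and leaving out each pair gave 86 to 230 and 67 to 437.

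Without the replicate block for the pairs, 17 genes rose and 28 fell, or 20 and 38 in the fit of all 15 samples. The deviations of paired samples correlated in 6 of 6 pairs, so the fit without the block counts shared variation as noise. With a replicate block by library code number, which no source describes as a pairing of uncultured samples, 2522 genes fell in control culture and 2757 in MLLT3 culture.

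For control against uncultured, 1635 genes rose and 4000 fell. Other settings gave 2498 and 2625 (median centring), 2492 and 2601 (quantile normalization), 2645 and 2347 (TMM factors), 367 and 534 (fold of at least 2) and 879 and 1690 (only libraries named like the uncultured ones, with fewer samples), and a filter of RPKM 5, with fewer genes tested, gave 1066 rises. Rises on rebuilt reads were 2945 (edgeR), 2868 (edgeR with DESeq2 size factors), 2934 (edgeR, no filter), 3047 (DESeq2) and 2894 (voom). Leaving out each library gave 1302 to 1664 rises and 2568 to 4138 falls.

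For MLLT3 against uncultured, 1628 genes rose and 4270 fell. Rises were 2514 (median centring), 2596 (quantile normalization), 2770 (TMM factors) and 340 (fold of at least 2), and falls 2828 (quantile normalization), 2508 (TMM factors), 545 (fold of at least 2) and 2215 (only libraries named like the uncultured ones). Rises on rebuilt reads were 3056 (edgeR), 2970 (edgeR with DESeq2 size factors), 2996 (edgeR, no filter), 3155 (DESeq2) and 2972 (voom). Leaving out each library gave 1309 to 1604 rises and 2885 to 4367 falls. Leaving out 1 of the 3 uncultured samples also drops genes found in these alone, since the filter asks for 3 samples, and the megakaryocyte, endothelial and fetal program lists lost their calls there; with the genes kept they did not.

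Camera called 14, 13 and 15 lists in the 3 comparisons, and 0 with an estimated correlation. Fry called 4 (stem cell, HOX, T and NK, small RNAs), 16 and 19, some not called by camera. Camera's direction reversed for the interferon-stimulated list in pairs 5 and 6 alone (MLLT3 against control, unadjusted p of 0.1681). It also reversed for endothelial genes (MLLT3 against uncultured) with a filter of RPKM 5 (unadjusted p of 0.8052). The authors' deposited table held 599 rises and 676 falls at an adjusted p under 0.01.

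Of the genes that fell in culture and rose with MLLT3 there were 126, against 28 (no filter), 80 (filter of RPKM 5), 198 (median centring), 203 (quantile normalization), 198 (TMM factors), 1 (fold of at least 2), 274 (edgeR), 278 (edgeR with DESeq2 size factors), 287 (edgeR, no filter), 271 (DESeq2), 311 (voom), 8 (no replicate block) and 15.5 (controls split 3 and 3). Of those that rose in culture and fell with MLLT3 there were 137, against 47 (no filter), 215 (quantile normalization), 209 (TMM factors), 5 (fold of at least 2), 352 (edgeR), 351 (edgeR with DESeq2 size factors), 396 (edgeR, no filter), 360 (DESeq2), 374 (voom), 18 (no replicate block) and 21 (controls split 3 and 3). The distance to the uncultured group (0.0089) reversed without replicate 3 (−0.0111), 4 (−4.76e-04) and 6 (−0.00594), and ran from −0.0111 to 0.0260 with each pair left out.

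For the called genes considered for naming, of which the text names only some, results over all settings kept direction and side of the threshold in 1004 cases for MLLT3 against control and lost the threshold in 322. The counts were 2152 and 64 for control against uncultured and 877 and 40 for MLLT3 against uncultured, and 0 reversed. Limits of the data are the 3 uncultured samples, a depth of 12.3 to 15.5 M tags at which low genes are known from few reads, and sources that do not say whether samples came from separate donors.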

Other observations

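No test in this part was chosen only after the result was seen; the values below are given without explanation.

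The difference of the MLLT3 effect between pairs 1 to 4 and pairs 5 and 6 was tested for every gene in limma. Of 12558 genes 0 differed past an adjusted p of 0.05, and 760 had an unadjusted p under 0.05. The 10 most abundant genes held 4.37% of exonic tags in the uncultured samples, 4.84% in controls and 5.57% with MLLT3 (n = 3, 6 and 6). The largest principal component of all samples held 48.8% of the variance. HOXA6 was called both with MLLT3 against control (0.51, SE 0.07, n = 6 pairs, adjusted p = 0.00589) and with MLLT3 against uncultured cells (1.47, SE 0.14, adjusted p = 9.11e-07).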
